A study of Mus musculus with 6 samples.

How the data were processed

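The series holds 6 bulk RNA-seq libraries from subcutaneous tumours of CT2A, a mouse glioma cell line, grown in mice: 3 libraries from Siglece knockout (KO) mice and 3 from wild-type (WT) mice. Per the labels' protocols, between 5000 and 20000 CT2A cells were taken per sample and libraries were made with Smart-seq2, a full-length cDNA method that does not mark the strand of the RNA. The labels name no sort or gate. They give the tissue as a subcutaneous tumour and the source as brain, and the tissue entry was followed here. Replicate numbers were given in accession order and only name a library.

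The authors deposited 1 table of raw read counts per gene for 55291 gene symbols, 1 column per library, with exon positions and merged exon lengths in the layout that featureCounts writes, per the file headers. Its values were whole numbers with totals that differed between libraries. Per the submitters' processing notes, the genome build was mm10 and DESeq2 was among the tools. The aligner, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Of the 55291 symbols, 52905 had the same symbol and position in GENCODE M21, which is on the same build. That annotation supplied gene identifiers, transcript sequences for GC content, and the classes of antigen receptor segments. Because strand was not marked, reads of a gene and of an antisense or overlapping gene cannot be told apart. Counts of near-identical copies are uncertain for another reason, the unknown treatment of reads with several alignments. Among the genes named here such copies are the immunoglobulin segments, Gzmd, H2-Q6, H2-M3, H2-D1, Klri2, Klra7, Hbb-bs, and the ribosomal protein and mitochondrially encoded genes.

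KO was compared with WT with the quasi-likelihood F test of edgeR 4.0.16 (two-sided, group as the only term, TMM normalization, filterByExpr with its defaults) in R 4.3.3, which left 18621 genes that held 99.9% of all counts. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Levels are CPM (counts scaled to the library total) on TMM-scaled library sizes, given as mean ± SD with n = 3 per group. Standard errors (SE) of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of F. Shares of counts were compared with an exact two-sided permutation test of the mean difference; with 3 against 3 libraries its smallest p is 0.1. The titles give each library its own tag, but the labels do not say whether the libraries of a group came from separate animals. P-values therefore measure the spread between these samples, which may be partly technical. Serial numbers in the column headers run in separate ranges for KO and WT, and what they stand for is not stated. If they mark an order of processing, it cannot be separated from genotype.

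Before the data were examined, 41 gene lists were written from textbook markers, covering immune, stromal, skin, fat, muscle, blood and brain cells and several pathways. They held 675 distinct genes, 620 of them tested, and 31 genes stood in more than 1 list. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Log2 CPM values per library used a prior count of 2.

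The genes named were set by a rule fixed at the same time: Siglece and the members of the Siglec family list; of the genes past the threshold with non-overlapping groups, a mean log2 CPM of 1 or more and a symbol that is not a predicted model, the 12 with the greatest fold change in each direction; and up to 4 members of each list with the smallest p. A few genes that this rule selects are not reported here. Xist and 3 cholesterol synthesis genes in the closing section were chosen after their values were seen, as was a list of 20 cholesterol synthesis genes.

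Library totals ran from 24369359 to 40574093 counts, so that 3 counts, taken as the limit a count of 0 allows, stood for 0.0820 to 0.150 TMM-scaled CPM. Reads carried no molecular identifiers, and intervals (95%) and limits cover counting error only. No 2 libraries agreed within sampling noise: the closest pair, WT replicates 2 and 3, had a chi-square of 10.2 per degree of freedom. No columns of the table were left out.

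The analysis was tested on simulated counts for the 18621 genes of KO against WT. Of 91 tested genes changed 4-fold, 34.1% were recovered, and of 92 changed 16-fold, 81.5%. In the same simulation 6 unchanged genes were called, 5.36% of the calls. Few genes were changed and each was drawn independently, so these shares need not carry over to the real libraries. When the T cell list was raised 4-fold in simulated counts, camera called it and 0 of the other lists; the simulated genes were independent, which real list members are not.

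Alternatives fixed in advance were RLE, upper-quartile and no composition scaling, no low-count filter and a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without sample quality weights, robust quasi-likelihood fitting, another threshold, sex-linked, receptor segment, haemoglobin and mitochondrial genes left out, each library left out in turn, and other set tests. Added after seeing the data were thinning to equal depth, leaving out KO replicate 2 and WT replicate 1 together, and leaving out each library under DESeq2 and limma-voom.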

Results

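Gene expression was measured by bulk RNA-seq in CT2A tumours, a mouse glioma line grown under the skin, in 3 libraries from Siglece KO mice and 3 from WT mice. Siglec-E, the product of Siglece, is an inhibitory sialic-acid-binding receptor of mouse myeloid cells. The series title places the mouse gene's human counterpart Siglec-9 as a checkpoint on macrophages in glioblastoma, and the design compares the tumours of KO and WT mice. Library totals were 30716367, 32162184 and 24369359 counts for KO replicates 1, 2 and 3. They were 40574093, 31062215 and 29673568 counts for WT replicates 1, 2 and 3.

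The targeted gene was examined first. Siglece (ENSMUSG00000030474.9) lies on the minus strand of chromosome 7 at 43651070 to 43660161 (mm10), with 1849 bases of merged exons and 7 exons in its longest transcript. It had 0, 8 and 0 counts in KO replicates 1, 2 and 3 and 74, 99 and 64 counts in WT replicates 1, 2 and 3. Its level was 0.0760 ± 0.132 CPM in KO and 2.25 ± 0.498 CPM in WT (SD, n = 3). The log2 fold change was -4.66 (SE 1.15, adjusted p = 0.0409, edgeR). The table counts whole genes, so the deleted part of the locus was not resolved, and the 8 counts of KO replicate 2 were not assigned to an exon. The adjusted p rose to 0.0513 without composition scaling. Again with all libraries, it was 0.000108 with DESeq2, 0.0403 with limma-voom, 0.000463 with limma-voom and quality weights, and 0.00559 with no low-count filter. It was 0.122, 0.0677, 0.124, 0.144 and 0.130 without KO replicate 1, KO replicate 3, WT replicate 1, WT replicate 2 and WT replicate 3, and 0.00275 without KO replicate 2. Siglece was lower in KO in each of these fits.

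**Figure D1:**
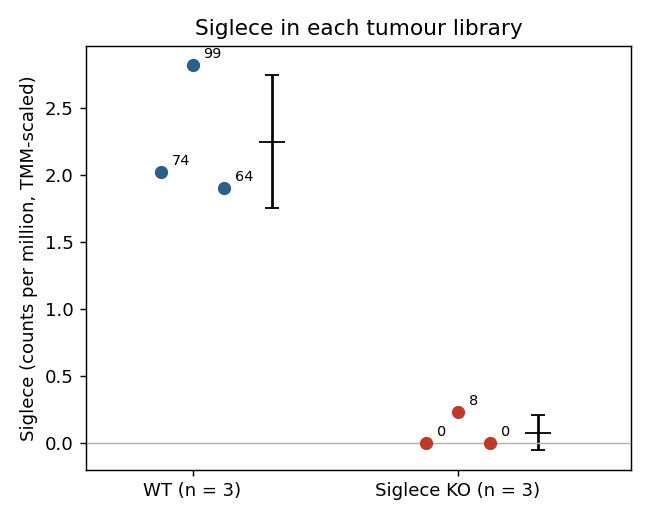
Siglece in each library, in TMM-scaled CPM, with the raw count beside each point; horizontal marks and bars are the group mean ± SD (n = 3). The KO libraries had 0, 8 and 0 counts, all below the WT libraries at 64 to 99.

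Of the 8 tested members of the Siglec family list, 5 were higher in KO and Siglece alone was lower (6 and 1 adjusted over the list alone). Cd22, a B cell inhibitory receptor, was at 48.0 ± 29.7 CPM in KO and 4.78 ± 0.865 CPM in WT, and Siglech, a marker of plasmacytoid dendritic cells, had a log2 fold change of 2.79 (SE 0.61). Cd33 (log2 fold change 1.58, SE 0.35), Siglecg (3.29, SE 0.83) and Mag (2.46, SE 0.57) were also higher. Siglec1 (1.77, SE 0.81, adjusted p = 0.174) and Siglecf (2.90, SE 0.97, adjusted p = 0.0930) did not pass, although Siglecf did with no low-count filter (0.0379), and Siglec15, at 0 to 9 counts per library, was below the filter and not tested (0.0570 CPM in KO, 0.184 CPM in WT). Per library, KO replicates 1, 2 and 3 had 4986, 2121 and 510 counts of Siglec1, 20, 37 and 147 of Siglecf, 104, 55 and 178 of Siglecg. The same libraries had 313, 170 and 351 counts of Siglech, 714, 606 and 666 of Cd33, 2029, 492 and 1224 of Cd22, and 285, 92 and 179 of Mag. WT replicates 1, 2 and 3 had 222, 1242 and 1128 counts of Siglec1, 15, 12 and 15 of Siglecf, 6, 21 and 22 of Siglecg. The same libraries had 91, 41 and 37 counts of Siglech, 234, 349 and 291 of Cd33, 189, 133 and 181 of Cd22, and 48, 46 and 41 of Mag. Siglecg missed the threshold under RLE scaling (adjusted p = 0.0503), and both Siglecg and Cd33 missed it without composition scaling (0.0597 and 0.0538). With limma-voom each of the 5 genes missed it (adjusted p from 0.0504 to 0.0744). The list was called higher by camera (adjusted p = 0.00793); the adjusted p was 0.354 with an estimated correlation.

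Across the transcriptome, 2083 genes were higher and 42 lower in KO tumours among 18621 tested. The genes with the greatest rise by the naming rule were led by immunoglobulin segments and the IgG1 constant gene, products of antibody-forming cells. Ighg1 was at 732 ± 582 CPM in KO and 7.43 ± 8.44 CPM in WT. Ighv1-81, Igkv1-117 and Igkv9-120 had log2 fold changes of 6.83 (SE 0.90), 6.80 (SE 1.37) and 6.03 (SE 1.49). Ighv1-9 had 321 counts over the KO libraries and 1 over the WT libraries, a ratio of 399.7 (95% counting interval 71.2 to 15837), and Ighv5-6 had 391 and 3 counts, a ratio of 162 (55.1 to 790.4). Of 39 tested immunoglobulin segments 22 were higher, and of 24 T cell receptor segments 6 were. The other named genes that rose were Cxcl5, a neutrophil-attracting chemokine, Gzmd, a granzyme, Clec3b, Akr1c14, Col6a6 and Slc40a1, the iron exporter ferroportin. Their means rested unevenly on the libraries: Cxcl5 was at 0.544, 2.19 and 80.6 CPM and Gzmd at 2.45, 9.26 and 129 CPM in KO replicates 1, 2 and 3, and Clec3b at 22.6, 4.64 and 201 CPM. Cxcl5 missed the threshold under RLE scaling, no composition scaling and robust fitting (adjusted p = 0.0533, 0.0545 and 0.0516), and without KO replicate 2 and WT replicate 1 (0.0596). With limma-voom 10 of these 12 named genes, all but Ighg1 and Ighv1-81, missed it, at adjusted p from 0.0571 for Slc40a1 to 0.250 for Cxcl5. Slc40a1 was at 32.0 ± 22.7 CPM in KO and 0.511 ± 0.283 CPM in WT. Akr1c14 and Col6a6 were at 4.30 ± 4.56 and 6.64 ± 7.30 CPM in KO and 0.0578 ± 0.0570 and 0.0959 ± 0.0358 CPM in WT.

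Among the genes that fell, Il11, a cytokine of the interleukin 6 family, was at 2.39 ± 2.51 CPM in KO and 23.6 ± 6.28 CPM in WT. Cspg5 and Cntn1, surface proteins of neural cells, had log2 fold changes of -3.22 (SE 0.84) and -2.98 (SE 0.64). Slc1a3, a glutamate transporter of astrocytes, was at 4.56 ± 3.68 and 21.2 ± 2.94 CPM. Enzymes of sterol synthesis were also lower: Cyp51 was at 51.0 ± 48.3 CPM in KO and 267 ± 17.0 CPM in WT, Msmo1 at 35.9 ± 27.6 and 159.5 ± 10.8 CPM, and Acat2 at 15.3 ± 4.83 and 52.1 ± 9.21 CPM. Acsl3, which activates fatty acids, and Slc5a3, an inositol transporter, had log2 fold changes of -2.26 (SE 0.49) and -1.92 (SE 0.42). Cda and Nebl had log2 fold changes of -2.70 (SE 0.70) and -2.41 (SE 0.61). Without composition scaling 7 of these 11 genes (Il11, Cspg5, Cda, Nebl, Cyp51, Slc1a3 and Msmo1) missed the threshold, at adjusted p from 0.0579 to 0.0759. Il11 and Cyp51 also missed it with robust fitting (0.0521 and 0.0512), and Cda with limma-voom (0.0531).

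**Figure D2:**
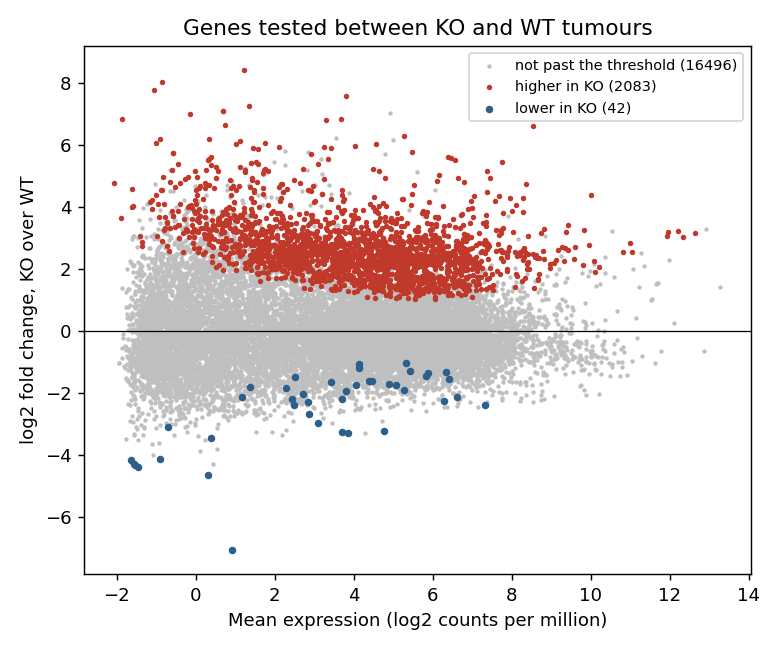
Log2 fold change of KO over WT against mean expression (log2 CPM) for each of the 18621 tested genes; coloured points passed an adjusted p of 0.05. The 2083 genes higher in KO lie over the whole range of expression and outnumber the 42 lower genes.

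The smallest adjusted p of any gene was 0.0246, and 8212 tested genes (44.1%) had groups that did not overlap. Chance gives 10% for a single gene. Genes move together and this share was not computed for other splits, so it does not by itself show an excess. The count depended on which libraries were in the fit: edgeR called 0 genes without KO replicate 1, WT replicate 1, WT replicate 2 or WT replicate 3. At an unadjusted p under 0.05 these fits gave 3461, 4931, 4282 and 4246 genes, while DESeq2 called 2084, 3099, 2569 and 2503, and limma-voom 0 each time. The count was 949 without KO replicate 3 and 8078 without KO replicate 2. Each of the 2125 genes was called again in the last fit. The edgeR counts of list members past the threshold over all genes fell to 0 in the same 4 fits. These counts also moved with other settings: of the T cell genes 11 were higher with limma-voom, 22 with DESeq2 and 9 without KO replicate 3, and of the macrophage genes 12, 19 and 5. The share of called genes that were higher in KO was 98.0% with edgeR, 72.4% of 4510 genes with DESeq2, 53.8% of 10280 genes with limma-voom and quality weights, and 55.1% without KO replicate 2.

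Libraries of the 2 groups differed in their makeup. The first principal component held 72.7% of the variance and placed KO replicates 1, 2 and 3 at -116, 17.7 and -178.5 and the WT replicates between 84.7 and 97.1. KO replicate 2 correlated across genes with WT replicates 2 and 3 at Pearson's r of 0.964 and 0.960 and with KO replicates 1 and 3 at 0.923 and 0.864; genes are not independent replicates. Mitochondrially encoded genes took 2.81 ± 1.38% of counts in KO and 0.985 ± 0.233% in WT, collagen genes 3.27 ± 1.39% and 0.873 ± 0.234%, and ribosomal protein genes 2.97 ± 0.716% and 5.46 ± 2.40% (exact two-sided permutation p = 0.1 for each, the smallest the design allows). WT replicate 1 held 8.24% of counts in ribosomal protein genes, and WT replicates 2 and 3 held 4.08% and 4.07%. The Y-linked genes Eif2s3y (47.4 ± 22.5 CPM in KO, 7.18 ± 0.807 CPM in WT), Ddx3y (52.9 ± 26.2 and 8.58 ± 1.37), Kdm5d (18.0 ± 7.36 and 3.15 ± 1.20) and Uty (16.4 ± 8.75 and 2.41 ± 0.903) were each higher in KO, while Xist, expressed from the inactive X of females, was at or below 0.595 CPM in each library. These 4 of the 5 sex-linked genes passed over all genes and adjusted over the list alone (camera adjusted p = 0.00120; with an estimated correlation, adjusted p = 0.354).

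T cell genes were higher in KO tumours. Of 22 T cell genes, 20 rose (22 adjusted over the list alone), among them Cd3e (47.7 ± 23.8 CPM in KO, 6.02 ± 0.597 CPM in WT), Cd4 (38.7 ± 22.2 and 4.77 ± 1.10) and the transcription factor Bcl11b (28.2 ± 18.0 and 2.09 ± 0.422). Of 20 cytotoxic effector genes 11 rose (16 adjusted over the list alone), including Tbx21, the T-bet transcription factor, and Klrk1, the NKG2D receptor, with log2 fold changes of 2.37 (SE 0.43) and 2.14 (SE 0.38). Of 16 activation and inhibitory receptors 10 rose (14 adjusted over the list alone), with Ctla4 at 22.5 ± 10.6 and 3.89 ± 0.355 CPM and Icos at 34.5 ± 20.7 and 5.25 ± 0.600 CPM. Of 9 regulatory T cell genes 5 rose (7 adjusted over the list alone), including Il2ra and Lrrc32 (log2 fold changes 2.51, SE 0.40, and 2.62, SE 0.43). Of 12 NK cell genes 3 rose (6 adjusted over the list alone), among them Klri2 (2.46, SE 0.59), and Klra7 did not pass (1.70, SE 0.49, adjusted p = 0.0648). Of 13 B and plasma cell genes 7 rose (adjusted over the list alone, 10 were higher and 1 lower), with Jchain, which joins polymeric antibodies, at 138 ± 102 and 4.19 ± 2.74 CPM, Mzb1 at 13.9 ± 10.7 and 0.596 ± 0.278 CPM and Blk at 6.93 ± 6.44 and 0.192 ± 0.0680 CPM. Camera called these lists higher, at adjusted p = 1.00e-13 for T cell, 1.76e-08 for cytotoxic effector, 7.31e-08 for receptor, 0.000127 for regulatory T cell, 0.00349 for NK cell and 0.000856 for B and plasma cell genes. With an estimated correlation the adjusted p was 0.371 for NK cell genes and 0.354 for the others.

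Myeloid genes were higher as well. Of 21 macrophage genes 16 rose (19 adjusted over the list alone), with Csf1r, the receptor for macrophage colony-stimulating factor, at 535 ± 280 CPM in KO and 102 ± 7.32 CPM in WT, and Cd68 at 471 ± 312 and 51.5 ± 7.56 CPM. Of 19 genes of alternatively activated macrophages 12 rose (15 adjusted over the list alone), including the folate receptor Folr2 (log2 fold change 2.99, SE 0.55) and the scavenger receptor Stab1 (2.54, SE 0.48). Of 19 phagocytosis and scavenger receptor genes 13 rose (15 adjusted over the list alone), including Mertk (3.14, SE 0.55), its ligand Gas6 (3.40, SE 0.51) and Sirpa (3.30, SE 0.59). The counts that rose were 6 of 12 for monocytes (11 adjusted over the list alone; Ccr2 1.95, SE 0.36), 4 of 9 for neutrophils (7 adjusted over the list alone; Csf3r 2.96, SE 0.48; Mmp9 2.98, SE 0.45) and 6 of 10 for mast cells (9 adjusted over the list alone; Tpsb2 2.85, SE 0.55; Gata2 2.24, SE 0.40). They were 8 of 18 for conventional dendritic cells (13 adjusted over the list alone; Flt3 2.62, SE 0.54; Clec10a 3.64, SE 0.80), 3 of 10 for plasmacytoid dendritic cells (7 adjusted over the list alone; Runx2 2.05, SE 0.39; Spib 2.22, SE 0.53) and 3 of 8 for microglia (7 adjusted over the list alone; Fcrls 1.63, SE 0.34). Camera called each of these 9 lists higher, with adjusted p from 8.40e-11 for macrophage to 0.00997 for plasmacytoid dendritic cell genes. With an estimated correlation the adjusted p was 0.354 for each. The neutrophil list rose most in KO replicate 3. Its means in KO replicates 1, 2 and 3 were 1.45, 1.55 and 4.11 above the WT mean on the log2 scale. Its median log2 fold change fell from 2.98 to 2.06 without KO replicate 3.

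Of 13 MHC class II genes 2 rose (3 adjusted over the list alone): Ctss, a protease that processes the invariant chain (log2 fold change 2.55, SE 0.63), and Ifi30, a lysosomal reductase (2.37, SE 0.55). In other settings 0 to 12 of the class II genes were higher (6 with DESeq2, 8 without KO replicate 2 and 12 with limma-voom and quality weights). H2-Aa did not pass (1.85, SE 0.56, adjusted p = 0.0736). Of 22 MHC class I genes 2 rose over all genes and adjusted over the list alone, H2-Q6 (2.16, SE 0.50) and H2-M3 (1.49, SE 0.35), both non-classical genes, and H2-D1 did not pass (4738 ± 1920.3 CPM in KO, 1674 ± 504.1 CPM in WT, adjusted p = 0.0930). The class I list was not called (camera adjusted p = 0.554); its median log2 fold change was -0.11 while its mean was 0.26. Of 17 co-stimulatory and co-inhibitory ligands 2 rose (7 adjusted over the list alone), Cd80 (2.11, SE 0.40) and Vsir (2.87, SE 0.53), and Cd274, the PD-L1 gene, did not pass (1.10, SE 0.29, adjusted p = 0.0511). Cd274 passed with the stricter filter (0.0441), after thinning (0.0492) and without KO replicate 2 and WT replicate 1 (0.0455). Of 23 chemokines 10 rose (14 adjusted over the list alone), including Cxcl12 (4.18, SE 0.67) and Ccl3 (2.56, SE 0.54). Of 17 inflammatory mediators 4 rose (8 adjusted over the list alone), including Tnf (1.63, SE 0.37) and Nlrp3 (2.05, SE 0.50). Camera called the class II list higher (adjusted p = 0.00276), as it did chemokines (3.47e-05), inflammatory mediators (0.00413) and the ligands (0.0452). With an estimated correlation the adjusted p was 0.457, 0.354, 0.354 and 0.375, and the ligand list was not called with the stricter filter (0.0753), with DESeq2 (0.0511), or without KO replicate 1, KO replicate 2, WT replicate 2 or WT replicate 3 (0.106, 0.0928, 0.0616 and 0.0768), or without KO replicate 2 and WT replicate 1 (0.112). Neither interferon list was called. Of 25 interferon gamma response genes 1 rose, Irf8 (1.72, SE 0.41), a factor that myeloid and dendritic cells also express, and 0 passed adjusted over the list alone; Nos2 did not pass (1.52, SE 0.42, adjusted p = 0.0558). Of the interferon gamma genes 3 were higher and 4 lower without KO replicate 2, and 5 higher and 7 lower with limma-voom and quality weights. Of 27 type I interferon response genes 0 passed over all genes or adjusted over the list alone (main edgeR fit), with Isg15 at 122 ± 80.2 and 237 ± 122 CPM and Oasl1 at 60.5 ± 36.2 and 31.5 ± 3.37 CPM. Of these genes 1 was called lower without KO replicate 2, and 2 higher and 3 lower with limma-voom and quality weights. The camera adjusted p was 0.319 and 0.0816 for the 2 interferon lists; the type I list was called lower with limma-voom (0.0495), without KO replicate 1 (0.00331) and without WT replicate 3 (0.0498). Without KO replicate 3 its median log2 fold change was 0.22 and it was not called (0.293). The type I list mean lay at 0.23, 0.27 and -1.87 relative to the WT mean in KO replicates 1, 2 and 3.

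Genes of vessels, connective tissue and muscle rose beside the immune genes, and fat genes did so mainly in KO replicate 3. Of 15 endothelial genes 13 rose (15 adjusted over the list alone), with Vwf at 116 ± 74.2 CPM in KO and 13.4 ± 0.695 CPM in WT and Kdr at 53.8 ± 4.09 and 12.6 ± 4.60 CPM. Of 21 fibroblast and matrix genes 17 rose (21 adjusted over the list alone), with the proteoglycan Dcn at 585 ± 367 and 41.3 ± 13.1 CPM and Col5a1 at 1127 ± 475 and 175 ± 37.5 CPM. Of 16 skeletal muscle genes 11 rose (15 adjusted over the list alone), including Atp2a1, the calcium pump of fast muscle (198 ± 147 and 14.4 ± 2.24 CPM), and Ttn (84.6 ± 53.7 and 8.86 ± 2.61 CPM). Of 11 pericyte and smooth muscle genes 6 rose (8 adjusted over the list alone; Pdgfrb 2.41, SE 0.39; Rgs5 3.02, SE 0.62), and of 12 adipocyte genes 4 rose (6 adjusted over the list alone; Lpl 5.17, SE 1.04; Fabp4 4.49, SE 1.14). Camera adjusted p was 3.54e-12 for endothelial, 1.58e-14 for fibroblast, 8.32e-09 for skeletal muscle, 0.000202 for pericyte and 0.00912 for adipocyte genes; with an estimated correlation the adjusted p was 0.487 for adipocytes and 0.354 for the others. The adipocyte list was not called with limma-voom and quality weights (0.0710). Its means in KO replicates 1, 2 and 3 were 0.64, 1.22 and 3.96 above the WT mean on the log2 scale, WT replicate 1 lay at 0.69, and its median log2 fold change fell from 2.95 to 0.81 without KO replicate 3. Fabp4 was at 97.6, 38.7 and 810.1 CPM in KO replicates 1, 2 and 3. Of 6 keratinocyte genes 1 rose (2 adjusted over the list alone), Sfn (2.56, SE 0.58), and of 5 erythroid genes 0 passed over all genes or adjusted over the list alone (main edgeR fit; Hbb-bs 2.64, SE 1.25). With no low-count filter 2 erythroid genes were higher, among them Hbb-bs (adjusted p = 0.0445), and without KO replicate 2, and with limma-voom and quality weights, 1 was. Neither list was called (0.487 and 0.282), and the erythroid list was called higher without KO replicate 1 (0.0138). Of 15 mitochondrially encoded genes 3 rose (12 adjusted over the list alone), including mt-Rnr2 (3.32, SE 0.77) and mt-Nd1 (2.53, SE 0.64; camera adjusted p = 6.35e-05; with an estimated correlation, adjusted p = 0.395). This rise was also uneven: mt-Rnr2 was at 185.0, 118.0 and 903.0 CPM in KO replicates 1, 2 and 3, and the list median fell from 2.24 to 1.11 without KO replicate 3.

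The cell cycle, ribosomal protein, unfolded protein response and hypoxia lists lay lower in KO as sets, and 0 of their genes fell past the threshold in the main edgeR fit. Other settings called members of these 4 lists lower. The counts were 10, 6, 2 and 8 with DESeq2, 25, 12, 9 and 14 with limma-voom and quality weights, and 4, 0, 0 and 3 with edgeR and no low-count filter. With edgeR they were 25, 1, 7 and 8 without KO replicate 2, and 24, 1, 6 and 10 without KO replicate 2 and WT replicate 1. Of 25 cell cycle genes 0 passed over all genes or adjusted over the list alone (main edgeR fit), and each had a negative log2 fold change, with Mki67 at 93.7 ± 59.0 CPM in KO and 241 ± 15.3 CPM in WT, Cdk1 at 65.1 ± 59.2 and 223 ± 64.3 CPM and Ccne2 at 10.1 ± 6.14 and 27.8 ± 1.34 CPM. The cell cycle list was called lower (camera adjusted p = 2.93e-08; with an estimated correlation, adjusted p = 0.371). Of 39 ribosomal protein genes 0 passed over all genes or adjusted over the list alone (main edgeR fit), with Rps4x at -1.42 (SE 0.54) and Rpl10 at -1.16 (SE 0.47). The list was called lower by camera (adjusted p = 0.000144, and 0.595 with an estimated correlation), but not without WT replicate 1 (0.0666) or without KO replicate 2 and WT replicate 1 (0.264). Its median log2 fold change went from -0.78 to -0.23 without WT replicate 1. Relative to the WT mean, its mean in KO replicate 3 (-0.245) lay above those of WT replicates 2 and 3 (-0.445 and -0.451). Of 15 unfolded protein response genes 0 passed over all genes or adjusted over the list alone (main edgeR fit), with the chaperone Hspa5 at -0.88 (SE 0.38), and the list was called lower (0.0163; with an estimated correlation, adjusted p = 0.354). The hypoxia and glycolysis list was called lower (0.0141; with an estimated correlation, adjusted p = 0.395; 0.0563 without KO replicate 1), while 2 of its 22 genes rose over all genes and adjusted over the list alone, Ndrg1 (2.88, SE 0.49), a stress-responsive gene, and Pfkfb3 (1.52, SE 0.37), an activator of glycolysis; Pfkl did not pass (-0.92, SE 0.30).

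The remaining lists were not called in the main analysis. Of 15 glioma and astrocyte genes 3 rose and 1 fell over all genes and adjusted over the list alone: Egfr (3.18, SE 0.50), Pdgfra (2.37, SE 0.57), which also stands in the fibroblast list, and Sox9 (2.96, SE 0.77) were higher, and Slc1a3 was lower (camera adjusted p = 0.0597). The list was called lower in 5 other settings. They were without KO replicate 2 (0.0116), without KO replicate 2 and WT replicate 1 (0.0367), with limma-voom (0.0308), with quality weights (0.0216) and with camera on ranks (0.0184). Of 6 neuron genes 2 rose (3 adjusted over the list alone), among them Camk2a (3.60, SE 0.76; list adjusted p = 0.848). Of 8 oligodendrocyte genes 1 rose over all genes and adjusted over the list alone, Mag, and Cnp did not pass (-0.89, SE 0.35; list adjusted p = 0.0727, and 0.0419, 0.0349 and 0.0396 without KO replicate 2, WT replicate 2 and WT replicate 3, and 0.0281 on ranks). Of 21 immediate early and heat shock genes 1 rose (0 adjusted over the list alone), Zfp36 (1.71, SE 0.42), and Fos did not pass (-1.19, SE 0.32, adjusted p = 0.0531; list adjusted p = 0.462). Fos passed under RLE scaling (0.0468), where 0 genes of the list were higher and 1 was lower. Of 27 oxidative phosphorylation genes 0 passed over all genes or adjusted over the list alone (main edgeR fit), with Cycs at -1.22 (SE 0.40; list adjusted p = 0.110, and 0.00778, 0.0142 and 0.0120 without KO replicate 3, WT replicate 2 and WT replicate 3). DESeq2 called 5 of these genes lower, and limma-voom with quality weights called 4 higher and 7 lower. With edgeR, Cycs passed with no low-count filter (adjusted p = 0.0484) and without KO replicate 2 and WT replicate 1 (0.00642), and 1 gene was higher and 3 lower without KO replicate 2. Of the genes named in these lists, Spib, Nlrp3, Pdgfra, Pfkfb3 and Zfp36 missed the threshold without composition scaling (adjusted p from 0.0508 to 0.0823), Sox9 and Zfp36 under RLE scaling (0.0541 and 0.0504), and Pdgfra without KO replicate 2 and WT replicate 1 (0.0530). With limma-voom 19 of the list members given as higher missed it (adjusted p from 0.0501 to 0.0963). They were Klri2, Mzb1, Blk, Folr2, Flt3, Clec10a, Spib, H2-M3, Irf8, Ccl3, Sfn, Lpl, Fabp4, Pdgfra, Sox9, Camk2a, Pfkfb3, Zfp36 and Uty. DESeq2 called 15 named genes that the main edgeR fit did not (adjusted p from 0.00500 to 0.0422). Siglecf, Klra7, H2-D1, H2-Aa, Cd274 and Nos2 were higher, and Mki67, Cdk1, Ccne2, Pfkl, Fos, Hspa5, Cycs, Rps4x and Rpl10 were lower. edgeR called 14 of these in other settings, all but Rpl10. With no low-count filter it called Siglecf, H2-Aa, Nos2, Cdk1, Ccne2, Fos and Cycs (adjusted p from 0.0246 to 0.0484). Without KO replicate 2 and WT replicate 1 it called Klra7, H2-D1, H2-Aa, Cd274, Mki67, Cdk1, Ccne2, Pfkl, Fos, Hspa5, Cycs and Rps4x, as well as Cnp and Xist as lower (adjusted p from 0.00461 to 0.0455). Siglec1 and Oasl1 passed as higher with limma-voom and quality weights. In all, camera called 31 of 41 lists, 27 higher and 4 lower; with an estimated correlation 0 were called (adjusted p from 0.354 to 0.856), and fry called 0 (lowest adjusted p = 0.0605).

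**Figure D3:**
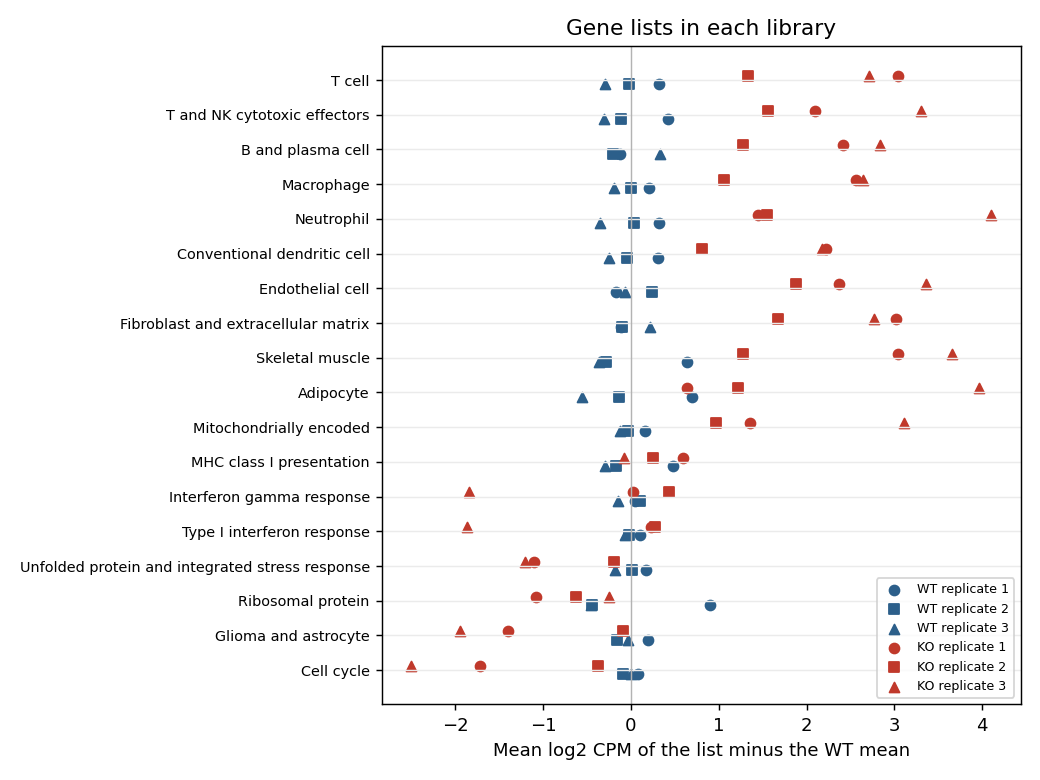
Mean log2 CPM of the tested members of 18 gene lists in each library, minus the mean of the WT libraries. KO replicate 2 lies between the WT libraries and the other KO libraries in most cell type lists (macrophage 1.05 against 2.56 and 2.65), and KO replicate 3 lies apart in both interferon lists (-1.85 and -1.87).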

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

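Thinning, leaving out KO replicate 2 with WT replicate 1, and leaving out libraries under DESeq2 and limma-voom were chosen after seeing the data. No paired analysis was possible because the labels carry no replicate numbers that tie KO to WT samples. The 2125 genes called (2083 higher, 42 lower) became 3356 (476 lower) with no low-count filter, 4510 (3266 and 1244) with DESeq2, 1019 (988 higher) with limma-voom, 10280 (5531 and 4749) with quality weights, 3772 (3281 and 491) at an adjusted p of 0.1 and 8809 (4711 and 4098) without KO replicate 2 and WT replicate 1; 24 were lower without composition scaling. Leaving out 1 library gave 0 to 8078 genes (0 to 4449 higher, 0 to 3629 lower) with edgeR, 2084 to 9351 with DESeq2 and 0 to 7966 with limma-voom. Fewer samples may be part of the cause of the lower counts, but leaving out KO replicate 2 raised the count with each tool. The cause was not tested. With edgeR, and with DESeq2 and limma-voom on all libraries, no shared call changed sign, and 99.2% of the calls were among those of DESeq2 and 47.4% among those of limma-voom. With all libraries thinned to the lowest total 2145 genes were called, so unequal depth does not account for the count. Under RLE, upper-quartile and no composition scaling, no called host cell type list had a median log2 fold change below 1.47; the median of all genes was -0.05 with TMM and -0.18 without composition scaling. The Siglece log2 fold change was -4.72 without composition scaling, where it missed the threshold, and -9.13 to -4.14 with 1 library left out; the value of -9.13, without KO replicate 2, comes from KO libraries at 0 counts and is no bound. Camera called 29 to 33 lists under the other settings and 0 with an estimated correlation or with fry. The mitochondrial share differed by 1.83 percentage points, and by 0.690 without the 50 most abundant genes. The ribosomal protein share differed by -2.50 points, and by -1.48 (permutation p = 0.3) without those genes. The removal did not spare mitochondrial or ribosomal protein genes, so part of each smaller difference may be built in. Lists whose direction in camera changed were all uncalled; their medians, which need not share its sign, were: Neuron (0.31 with limma-voom, 0.61 without the 2 libraries, 0.67 on ranks, all above 0 as in the main fit), interferon gamma (-0.0075), type I interferon (0.22) and erythroid (-0.13) without KO replicate 3, MHC class I (-0.19) without WT replicate 3, keratinocyte (-1.91) after thinning, and oxidative phosphorylation (0.28) without the 2 libraries; the cause was not tested. With 1 library left out in turn, the medians ran from -0.996 to -0.0075 for interferon gamma and from -0.60 to 0.22 for type I interferon. They ran from -0.13 to 2.81 for erythroid and from -0.22 to 0.11 for MHC class I genes. Of the called values, 432 gene and 6 list values with 1 library left out, and 62 and 67 under the other settings, kept their direction but missed the threshold. At this depth a gene under about 0.150 CPM cannot be told from absent.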

Other observations

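The tests of the host cell share, of Xist, of the Siglece label and of Y-linked genes in KO replicate 3 were chosen only after the results were seen, as were the set of 16 host cell type lists and the cholesterol list below. Genes of cholesterol synthesis lay lower in KO tumours. Of 20 such genes 6 fell (Acat2, Dhcr7, Hmgcs1, Msmo1, Nsdhl and Cyp51), against 42 of all 18621 tested genes (Fisher's exact test, two-sided, p = 3.43e-12), and 19 had a negative log2 fold change, with a median of -1.53. Dhcr7, Hmgcs1 and Nsdhl, chosen after their values were seen, had log2 fold changes of -1.35 (SE 0.27), -1.32 (SE 0.29) and -1.19 (SE 0.31). The list was written because some of its genes had been seen among the lower genes, so this p is not independent evidence; camera gave an adjusted p of 7.10e-09 over 42 lists, and 0.348 with an estimated correlation. Without composition scaling Msmo1, Nsdhl and Cyp51 missed the threshold (0.0579, 0.0700 and 0.0759), as Nsdhl did with limma-voom (0.0606). The list mean in KO replicates 1, 2 and 3 lay at -1.93, -0.98 and -2.05 relative to the WT mean, in mirrored order to the Y-linked means (2.97, 1.54 and 3.09), as were the cell cycle list (-1.72, -0.37 and -2.50) and the glioma and astrocyte list (-1.40, -0.09 and -1.95). Whether these falls only follow the share of host cells was not tested.

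Markers of most host cell types were higher in KO libraries. A larger share of host cells in the KO samples is a candidate explanation. The median of 16 host list medians was 2.41 (SD 0.492) and that of the 4 Y-linked genes 2.67, a difference of -0.27. Subtracting the Y-linked mean of each library lowered the median absolute KO to WT difference of the lists from 1.97 to 0.563. The Y-linked genes rose in KO themselves. Subtracting them shrinks any list that rose by a like amount, whatever the cause, so the drop cannot decide between causes. The comparison also takes Y-linked transcripts to come from host cells only, and whether CT2A cells express them was not tested. Xist at no more than 0.595 CPM in a WT library argues against female WT mice, and the lists kept a median of 99.7% of their change after removal of a length and GC trend. After the subtraction all lists but endothelial (8.5e-05) and skeletal muscle (0.12) turned from higher to lower in KO, most with overlapping groups. Of the 16 lists 3 (macrophage, conventional dendritic cell and pericyte) turned lower without overlap (exact permutation p = 0.1, the smallest possible, adjusted 0.174). Chance gives 10% for a list taken alone. Of all 40 lists compared, tumour and pathway lists included, 23 had non-overlapping groups after the subtraction. Microglia (KO minus WT -1.10) and regulatory T cell genes (-0.81), outside the set of 16, were among them and turned lower. The gap was narrow for macrophage (highest KO library 3.709, lowest WT library 3.716) and pericyte genes (1.286 and 1.329). Whether host cell types moved alike stays open. The keratinocyte list turned lower without overlap too, but with means of -0.90 to 0.08 log2 CPM, near the floor, it decides nothing. The labels speak of CT2A cells being sampled and name no sort; if tumour cells alone were meant, the host transcripts would be carried over with them. Whether genotype, tumour size or the sampling set the host share is untested, since host cell markers and genotype differ together in these 6 libraries.

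KO replicate 2 lay closer to the WT libraries than to the other KO libraries. Its Siglece count of 8 (upper 95% limit 15.8) is far below the 88.9 counts expected from its macrophage counts at the lowest WT ratio, which argues against a WT library under a KO label; an earlier bound for this test lay under 0 and was replaced after the value was seen. Had an unmixed KO replicate 2 matched the mean of the other KO libraries, mixing with WT RNA would need a median share of 72.7%. At the mean WT level of Siglece, its count allows at most 19.97%. A smaller share, 10.1% at the observed count, stays open. On these untested assumptions, mixing alone would not account for the place of KO replicate 2. A smaller share of host cells in that sample may account for it: 37.6% of its median gap to the other KO libraries was left after subtracting the Y-linked mean, with the sign turned (1.08 before, -0.41 after). Its Y-linked mean was itself below those of the other KO libraries. The subtraction therefore narrows any gap of like size, and cannot decide the cause.

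Both interferon response lists were low in KO replicate 3. The median type I gene lay at -2.18 and the median interferon gamma gene at -2.21 on the log2 scale relative to the mean of KO replicates 1 and 2, and 27 of 27 and 22 of 25 genes were lower. If Y-linked transcripts come from host cells only, which was not tested, fewer host cells would lower the Y-linked genes too. Their mean was 5.28 log2 CPM, against 5.16 and 3.74 in KO replicates 1 and 2, and so 1.54 above the lower of these. The check also takes the interferon genes to follow the host share. The type I list mean was 7.28 in KO replicate 1 and 7.06 in WT, although the Y-linked genes were higher in KO. A loss hitting genes of like abundance is argued against by the matched random lists, of which 0 of 10000 (percentile 0) had a type I median as low, although random lists do not hold co-regulated genes. KO replicate 3 also had the fewest genes detected (20953, against 24288 to 26913 in the others), the highest mitochondrial share (4.40%, against 0.717 to 2.11%) and the highest share in the 50 most abundant genes (22.9%), so an effect of sample quality on these genes in particular stays open. A lower interferon response in that tumour remains a hypothesis in 1 library, with no biological explanation tested.

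The 2125 genes were compared with other splits of the 6 libraries into 3 and 3. Of 10 splits, 1, the real one, called as many, and the highest of the others called 0; 10 splits are too few for a share under 0.05.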
